A study of Hermetia illucens with 16 samples.

How the data were processed

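Fat body RNA was measured by polyA RNA-seq in larvae of the black soldier fly, Hermetia illucens, whose larvae are reared on organic waste. The fat body is the insect organ that stores nutrients, runs much of the metabolism and secretes antimicrobial peptides. Per the labels' protocols, larvae spent 10 days on a sterile Gainesville diet, a standard cereal-based fly diet, and were then divided into replicates of 50 larvae in 25 g of diet. Each replicate received 50 ml of liquid: sterile water for the control, 10 ml of a commercial Beauveria bassiana product with 40 ml of water, or 1 g of yeast pellet (Saccharomyces cerevisiae or Candida tropicalis) in sterile water. The fat bodies of 5 larvae per replicate were collected 4 days after treatment, and libraries were made with a NEBNext Ultra II kit after polyA selection. There were 4 replicates per group and 16 libraries, grouped by sample title.

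The authors deposited a table of whole-number counts per gene, which were not normalized. STAR and Salmon are named in the submitters' processing notes, without versions; the role and order of each, the genome build and the annotation are not given in the sources used here. Because Salmon estimates counts, the deposited counts may have been rounded from estimates. The table held 15328 entries. Of these, 15309 matched the gene symbols of the RefSeq gene table for assembly iHerIll2.2, which was used only for gene biotypes and for which genes neighbour each other, so that no coordinates are printed. The remaining 19 entries carried names of antimicrobial peptides (17 defensins and 2 knottin-like peptides). They may overlap RefSeq genes or one another, and reads shared between near-identical copies may have been divided among them, so the value of any single defensin entry is uncertain to that extent.

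Total counts ran from 8164488 to 25628756 per library. In edgeR 4.0.16 (R 4.3.3), filterByExpr on group kept 10031 genes. TMM factors were computed, dispersions were estimated robustly (common biological coefficient of variation 0.631), and quasi-likelihood F tests (two-sided) were run in one fit over all 16 libraries with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. For the antimicrobial list, p values were also adjusted over the list alone. CPM values are counts scaled by the TMM-adjusted library size. Log2 folds are given ± a standard error worked back from the log2 fold and its F statistic, so it adds nothing to the p value. CPM means are given ± SD. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera asks whether the list moves differently from the other genes, and fry whether the list itself moves. With a single list, its adjusted p equals its p. Single library measures were compared by exact two-sided permutation tests, whose smallest p with 4 against 4 libraries is 0.0286.

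Groups, designs, tests, gene lists and most alternatives were fixed before the data were examined. The 29 fixed lists were to be matched on product descriptions, or on symbols where there are none. The table used here gives numbered LOC symbols without descriptions, so the antimicrobial list alone had members (10 of its 19 entries were tested) and the other 28 lists are void, including 7 marker lists of other tissues. The admixture of other tissues in the dissections was therefore not tested. The antimicrobial list is cut short as well, since only entries named as defensin or knottin matched. Names of other families that it was to include, such as cecropin and attacin, matched nothing. Any such genes under LOC symbols are not on the list. The rule for named genes was as follows. From the antimicrobial list it took the members past the threshold, or the 4 with the lowest p where none passed. From all genes it took the largest rises and falls among called genes with a descriptive name, at least 5 CPM in the higher group and no overlap between groups. From each fixed list with called members it took those with the lowest p. The condition of a descriptive name could not be applied. The LOC genes named here, at most 2 in each direction per comparison, are those with the largest called folds, or the lowest p where nothing was called, and they were chosen after their values were seen.

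The tests were tried on simulated data, with counts drawn for the real genes and library sizes and 200 genes changed. For B. bassiana against control, 8% of the genes changed 2-fold, 56% of those changed 4-fold, 68% at 8-fold and 88% at 16-fold were recovered. For S. cerevisiae against control these shares were 16%, 58%, 66% and 86%, and for C. tropicalis against control 12%, 64%, 68% and 80%. For B. bassiana against C. tropicalis they were 8%, 66%, 76% and 86%, for B. bassiana against S. cerevisiae 18%, 70%, 70% and 78%, and for C. tropicalis against S. cerevisiae 6%, 56%, 66% and 92%. Between 2 and 7 unchanged genes were called per comparison.

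Replicate numbers come from the sample titles, and all 4 groups share them. For B. bassiana and control, the deviations of same-numbered libraries from their group means correlated over genes at a mean of 0.482 (lowest 0.152, highest 0.813), above 0.1 for all 4 numbers, so these numbers were taken to pair the 2 groups. The reported fits still had group as the only term. The pairing entered only through the replicate block among the alternatives and through the tests of the pairing itself. The other 5 pairs of groups did not meet that mark. Chance pairing was tested in 3 ways: within these 2 groups alone (1 of 24 pairings as high, left aside because the pair was picked for its correlation), by the highest of the 6 pairs of groups, and by the mean over all 6; only the last was chosen before the result was seen. After the data were seen, replicates 1 and 2 were also set against 3 and 4 within groups, by exact tests of 8 library measures (1296 placings) and by an added edgeR term (100 placings, the real one included). No library pair agreed within sampling noise (chi-square per degree of freedom of at least 76.6), so all 16 counted as separate samples.

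The alternatives set beforehand were median-of-ratios factors, DESeq2 1.42.0, limma voom with sample quality weights, no low-count filter, a stricter filter (at least 1 CPM in 8 libraries), a fit of the 2 groups compared alone, the replicate block, a log2 fold of at least 1, and leaving out each library of either group. Chosen after seeing the data were the block within 2 groups, the block of replicates 1 and 2 against 3 and 4, 3 surrogate variables (sva 3.50.0), thinning to the depth of the shallowest library, leaving out C. tropicalis replicate 1 together with control replicate 2, leaving out libraries of the groups not compared, adding the counts of Hill_BB_C308 to Hill_BB_C309, the list test between fungi, and the alternatives of the count adjusted over the list alone.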

Results

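The series asked how a fungus that infects insects and yeasts that are not known as insect pathogens alter antimicrobial peptide transcripts in the larval fat body. Beauveria bassiana is a mould used as a biological insecticide, S. cerevisiae is baker's yeast, and C. tropicalis is a yeast that can infect humans. Each of these groups and the untreated control had 4 libraries, taken 4 days after the fungus was added to the diet. Total counts per library ran from 10340889 to 24168738 in the control, from 8164488 to 14289384 with B. bassiana, from 13122897 to 20495150 with S. cerevisiae and from 8741144 to 25628756 with C. tropicalis.

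Libraries of one group were spread widely, and the groups did not separate as a whole in permutations that placed the libraries freely. Group membership accounted for 22.4% of the variance in log2 CPM, where chance gives 20% (permutation test, p = 0.273). Of the 6 pairs of groups, B. bassiana and C. tropicalis were the furthest apart, at 27.0% of variance against 14.3% by chance (exact permutation p = 0.0571, adjusted p = 0.343). These permutations took no account of the difference between replicate numbers given below, or of the paired numbers of B. bassiana and control. They therefore do not show that the groups were alike. The number of genes detected at a common depth, the shares of mitochondrial, ribosomal, pseudogene and long non-coding RNA, and the share taken by the 10 most abundant genes of each library were compared between groups. No such difference passed an exact permutation test after adjustment over 48 comparisons. With a smallest possible p of 0.0286, a single complete separation could not have passed, so this does not show that the groups were alike. Replicates 1 and 2 differed from replicates 3 and 4 in every group, a split chosen after the data were seen: in each of the 4 groups both had lower total counts and fewer genes detected at a common depth (medians 10746 and 11458, exact permutation p = 0.00154 and adjusted p = 0.00617 for both measures). Over all libraries their long non-coding RNA share was lower (permutation test, adjusted p = 0.0329) and their pseudogene share higher (adjusted p = 0.0432). In edgeR a term for this split called 1350 genes, where dividing the numbers as 1 and 3 against 2 and 4 or as 1 and 4 against 2 and 3 called 0. With that term in the fit, the comparisons below gave 52 genes for B. bassiana against C. tropicalis and 0 for each of the other 5, and within replicates 3 and 4 alone they gave 1 and 0, within 1 and 2 alone 0. Single libraries stood out too. In C. tropicalis replicate 1, COX1 and COX2, which encode subunits of mitochondrial cytochrome c oxidase, had 53.8 and 8.67 CPM, against medians of 9018 and 4327 CPM in the other libraries. In control replicate 2, 14.6% of counts were ribosomal RNA and 5.95% came from pseudogenes.

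**Figure D1:**
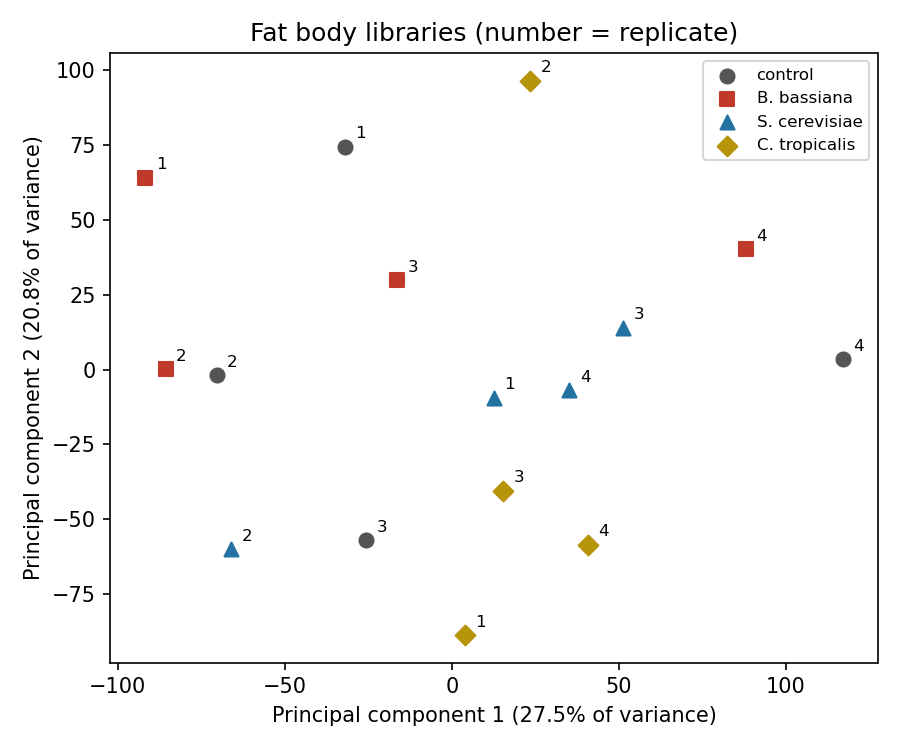
Principal components of log2 CPM over 10031 genes, with the share of variance on each axis; each point is 1 library, coloured by group and numbered by replicate. The groups overlap on both axes (27.5% and 20.8% of variance), and control 4 and B. bassiana 4 lie furthest to the right.

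Defensins, small cysteine-rich antimicrobial peptides, were transcribed in every group, the untreated larvae included. Of the 19 antimicrobial entries 10, all of them defensins, had enough counts to be tested. Antimicrobial genes of other families that carry LOC symbols are not covered by the counts of antimicrobial genes below. Hill_BB_C1619 alone took 72.1% of all counts on the list. It stood at 575 ± 51.7 CPM in control larvae, 428 ± 239 with B. bassiana, 327 ± 18.3 with S. cerevisiae and 584 ± 163 with C. tropicalis (SD, n = 4 each). Hill_BB_C309 followed at 120 ± 26.4, 53.1 ± 29.7, 122 ± 36.9 and 188 ± 174 CPM in the same order, then Hill_BB_C13793 at means of 21.8, 20.6, 18.0 and 22.8 CPM and Hill_BB_C6571 at 11.4 ± 10.5, 5.48 ± 3.87, 13.4 ± 7.82 and 29.2 ± 19.3 CPM. Hill_BB_C308 had counts in 5 of the 16 libraries and 0 in the others, although Hill_BB_C309 was counted in all 16, so both values are uncertain. Both knottin-like entries had 0 counts in all libraries, which allows up to 0.012 CPM over the whole set, for counting error only.

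**Figure D2:**
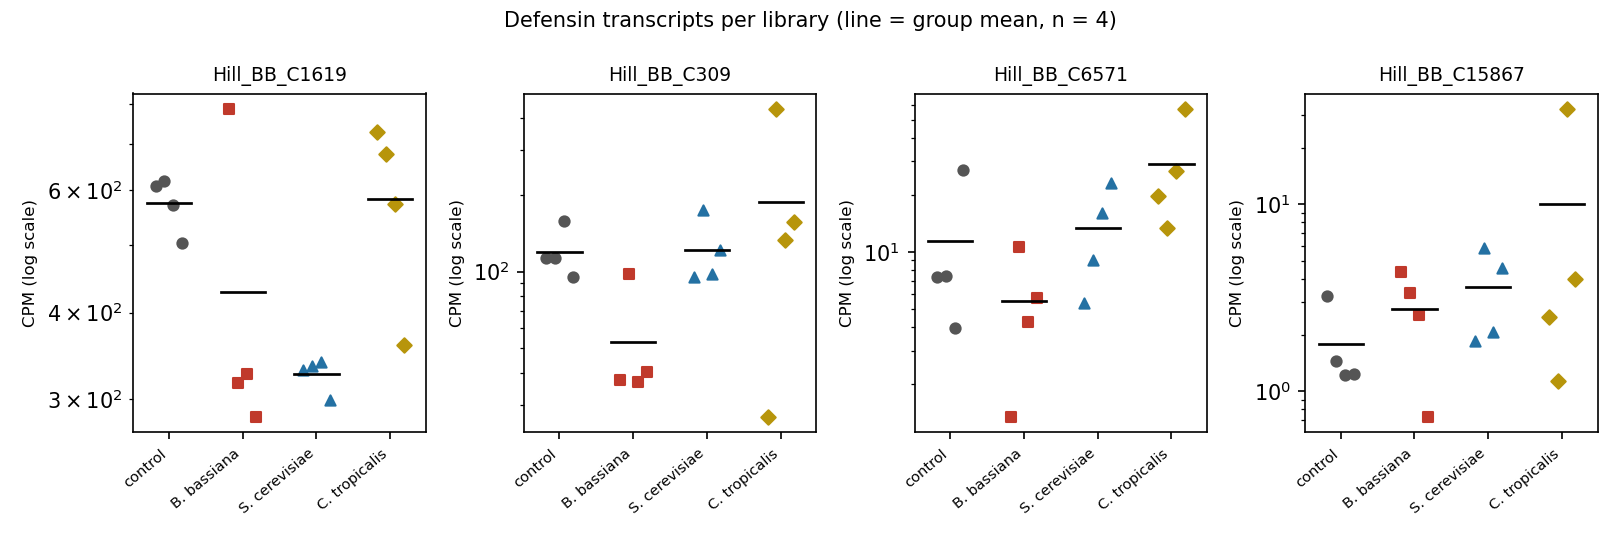
CPM on a log axis of 4 defensin entries in each library, by group; points are libraries and lines are group means (n = 4). All 4 S. cerevisiae libraries lie between 299.8 and 340 CPM for Hill_BB_C1619, below the control libraries at 504 to 619 CPM.

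The first comparison set larvae given the product of the insect pathogen B. bassiana against untreated larvae. The control received water only, so the fungus cannot be told apart from the rest of the product in any B. bassiana comparison. No gene passed the threshold in edgeR, and neither over all genes nor adjusted over the list alone did an antimicrobial gene (0 at an unadjusted p under 0.05, and 0 calls over all genes in DESeq2 and limma voom). Of the 10 tested defensins 7 had folds below 0 and 3 above, with a median log2 fold of -0.33. Hill_BB_C309 had a log2 fold of -1.17 ± 0.59 (edgeR adjusted p = 0.767), Hill_BB_C6571 of -1.06 ± 0.70 (-0.18 without control 4, at 26.9 CPM against 3.97 to 7.46) and Hill_BB_C1826 of -1.16 ± 1.16 (-1.86 without B. bassiana 2). The abundant Hill_BB_C1619 had -0.43 ± 0.31 (-0.90 without B. bassiana 1), with replicate 1 at 786 CPM and the other 3 at 283 to 326 CPM. As a list the defensins were lower than other genes by limma's camera (adjusted p = 0.0495), but not with an estimated correlation (adjusted p = 0.169) or by fry (adjusted p = 0.223). With the replicate number as a block the camera adjusted p was 0.0200, and edgeR still called 0 genes. Among all genes the lowest p values belonged to LOC119648756 (67.5 ± 61.6 CPM against 1.06 ± 0.606, log2 fold 6.01 ± 0.89, edgeR adjusted p = 0.107) and LOC119657269 (log2 fold 5.33 ± 0.91, adjusted p = 0.129) on the higher side. On the lower side they belonged to LOC119651378 (-1.17 ± 0.19) and LOC119658008 (-1.52 ± 0.28), both also at an adjusted p of 0.129. The 10 genes most abundant over all libraries had a median log2 fold of -0.95, with 9 of 10 below 0 and none past the threshold. They include the ribosomal RNA genes CGW64_mgr02 (-0.08) and LOC119661053 (-0.52) and the pseudogene LOC119661054 (-0.79), all on the lower side.

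At an unadjusted p under 0.05 there were 674 genes in edgeR, and DESeq2 called 150, limma voom 1 and the edgeR fit 0 genes, or 408 with surrogate variables. Without B. bassiana replicate 2 edgeR called 11 genes and without replicate 4 it called 7, the list-alone count was 1 without replicate 1, and the camera p exceeded 0.05 without control 1, 2 or 4 or B. bassiana 2, 3 or 4, reaching 0.633 without control 4.

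The second comparison set S. cerevisiae, the yeast used in baking, against untreated larvae. No gene and no antimicrobial gene passed the threshold in edgeR (1 defensin at an unadjusted p under 0.05, and 0 called over all genes in DESeq2 and limma voom). Hill_BB_C1619 came nearest on the list: it was lower in all 4 yeast libraries than in any control library, with a log2 fold of -0.82 ± 0.31, an edgeR adjusted p of 1 over all genes and of 0.191 adjusted over the list alone. Folds of the other defensins went both ways (5 of 10 above 0 in all, median log2 fold -0.02). Examples are Hill_BB_C1827 at 1.26 ± 1.00 (2.42 without control 4) and Hill_BB_C15867 at 1.02 ± 0.88. The list did not stand apart by limma's camera (adjusted p = 0.862). LOC119651047 had the lowest p of all genes, with 3.96 ± 5.29 CPM (0.0887 to 11.6) against 0.0128 ± 0.0256 and an adjusted p of 1, and it had almost no counts in the controls. LOC119654637 was at 5.27 ± 1.00 CPM against 12.4 ± 3.18 (log2 fold -1.23 ± 0.33, edgeR adjusted p = 1). The edgeR fit gave 0 calls and 157 genes at an unadjusted p under 0.05, DESeq2 called 3 and limma voom 0. The list-alone count was 0, and it became 1 in a fit of these 2 groups only and without B. bassiana replicate 1.

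The third comparison set C. tropicalis against untreated larvae. Here 9 of the 10 tested defensins had folds above 0, with a median log2 fold of 0.98, but none passed the edgeR threshold on its own, over all genes or over the list alone (1 at an unadjusted p under 0.05, and 0 called over all genes in DESeq2 and limma voom). Hill_BB_C15867 had the lowest p, at 9.99 ± 14.9 CPM against 1.79 ± 0.976 (log2 fold 2.51 ± 0.91, edgeR adjusted p = 0.9999 over all genes and 0.156 over the list alone), with 32.3 CPM in replicate 3 and 1.13 to 4.01 CPM in the other 3, and a log2 fold of 0.55 without replicate 3. Hill_BB_C6571 had a log2 fold of 1.35 ± 0.70 (2.23 without control 4, 0.81 without C. tropicalis 4), Hill_BB_C1826 of 1.82 ± 1.04 (1.12 at one common depth) and Hill_BB_C1827 of 1.31 ± 1.00 (2.49 without control 4, 0.25 without C. tropicalis 4), and the abundant Hill_BB_C1619 of 0.02 ± 0.31. As a list the defensins were higher than other genes by limma's camera (adjusted p = 0.0250), but not with an estimated correlation (adjusted p = 0.120). Of all genes, LOC119651361 (31.6 ± 13.9 CPM against 9.25 ± 3.51, log2 fold 1.77 ± 0.36) and LOC119652775 (593 ± 233 CPM against 284 ± 97.3, log2 fold 1.07 ± 0.31) had the lowest p values on the higher side, and LOC119658255 (log2 fold -2.03 ± 0.48) on the lower, all at an edgeR adjusted p of 0.9999. The 13 mitochondrial protein genes had a median log2 fold of -0.41, none past the threshold, and replicate 1 of this group is the library low in COX1 and COX2. The edgeR fit gave 0 calls and 290 genes at an unadjusted p under 0.05, DESeq2 called 13 and limma voom 0. The camera p exceeded 0.05 without control 3 (adjusted p = 0.416), C. tropicalis 2 or C. tropicalis 3, and in DESeq2 Hill_BB_C15867 passed over the list alone.

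No gene changed the same way under all 3 fungi in edgeR, with 674, 157 and 290 genes at an unadjusted p under 0.05 in the separate comparisons, and DESeq2 gave 1 such gene and limma voom 0. Across the 10031 genes, which are not independent replicates, log2 folds of the B. bassiana and S. cerevisiae comparisons correlated at r = 0.19, those of B. bassiana and C. tropicalis at -0.10, and those of S. cerevisiae and C. tropicalis at 0.30. Shared control libraries with no effect at all gave r = 0.50 for each pair in simulation. The covariances were 0.10, -0.06 and 0.13, against a simulated 0.31 for each pair, so that they lay below it by 0.21, 0.37 and 0.18. With 2 control libraries for one comparison and the other 2 for the other, the mean r was -0.34 (-0.46 to -0.16 over the ways to divide them), -0.47 (-0.56 to -0.32) and -0.37 (-0.46 to -0.29), where no effect at all gave values between -0.076 and 0.081 in simulation. The simulated libraries were independent, so these values leave out the paired numbers of B. bassiana and control and the difference of replicates 1 and 2 from 3 and 4. Both may shift the covariances, which was not tested.

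The fungi were then compared with each other. Between B. bassiana and C. tropicalis larvae, 48 protein-coding genes passed the threshold in edgeR, 19 higher and 29 lower with B. bassiana. The count was 0 in a fit of these 2 groups only, with the replicate block and without S. cerevisiae 1, and chance was not excluded. LOC119649290 was at 329 ± 186 CPM with B. bassiana and 1.01 ± 0.770 with C. tropicalis (log2 fold 8.36 ± 1.44, edgeR adjusted p = 0.0325), with control larvae at 34.6 ± 42.9 and S. cerevisiae larvae at 43.6 ± 30.0 CPM. LOC119648756 was at 67.5 ± 61.6 against 0.407 ± 0.0893 CPM (log2 fold 7.34 ± 0.96, adjusted p = 0.0251). LOC119647826, among the 10 most abundant genes of the tissue, was at 883 ± 738 CPM with B. bassiana, and at 47940 ± 23760 with C. tropicalis, 29890 ± 24360 with S. cerevisiae and 40000.0 ± 28970 in control larvae; its log2 fold between the 2 fungi was -5.76 ± 1.14 and its adjusted p 0.0482. LOC119656500 was at 21.7 ± 13.5 against 421 ± 230 CPM (log2 fold -4.28 ± 0.68, adjusted p = 0.0325).

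The 48 genes had no overlap between the groups in the 8 libraries, which their selection in these same libraries largely fixes. Of all tested genes 6.74% showed no overlap, where chance gives 2.86%. The median log2 fold was 3.46 for the higher and -1.49 for the lower genes. In the comparison of B. bassiana with control, all 19 higher genes also had folds above 0 and all 29 lower genes below 0, but none passed the threshold there, and both comparisons use the same B. bassiana libraries. For C. tropicalis against control, 18 of the 19 were below 0 and 28 of the 29 above 0, which is expected in part because the genes were selected in the same C. tropicalis libraries.

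**Figure D3:**
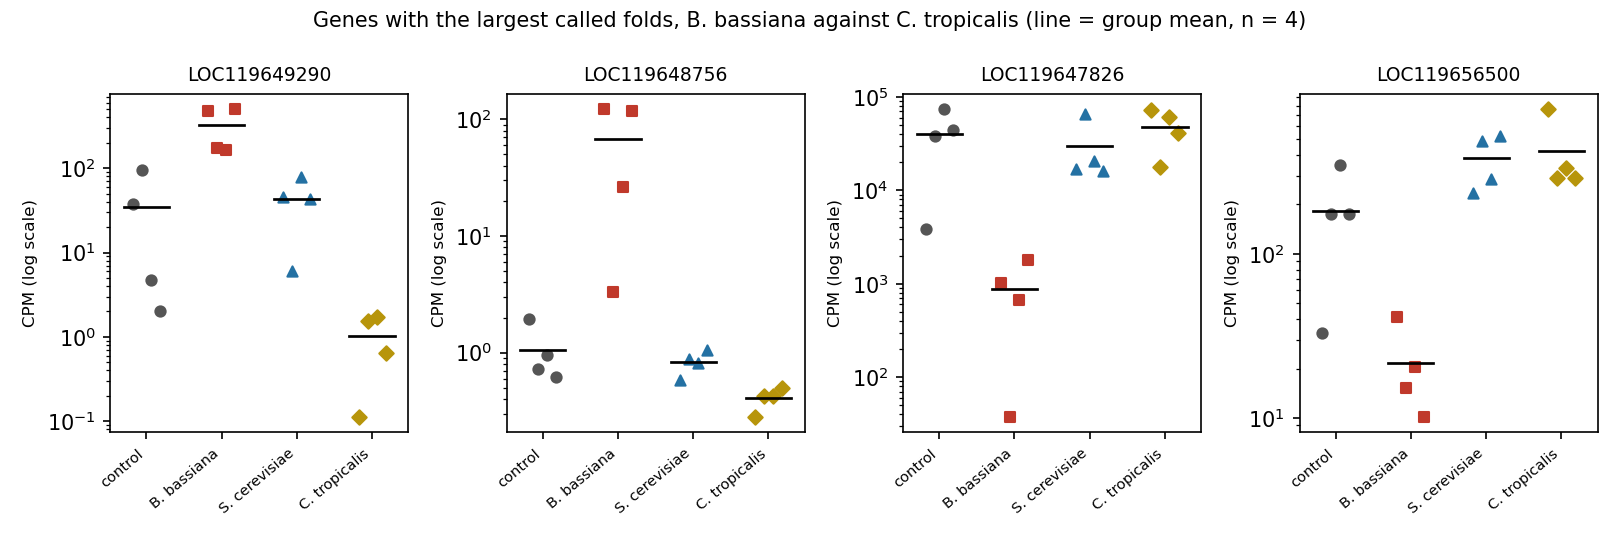
CPM on a log axis in each library, by group, of the 4 genes with the largest called folds between B. bassiana and C. tropicalis; lines are group means (n = 4). For LOC119647826 the B. bassiana libraries lie between 37.8 and 1809 CPM, and the libraries of the other groups between 3840 and 74490 CPM.

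Defensins were lower with B. bassiana than with C. tropicalis in 9 of the 10 fitted folds, with a median log2 fold of -1.49. No defensin passed over all genes in edgeR (3 of 10 at an unadjusted p under 0.05), where DESeq2 called 2 and limma voom 1. Adjusted over the list alone, 2 passed: Hill_BB_C6571 fell by 2.41 ± 0.73 on the log2 scale, and Hill_BB_C309 fell by 1.82 ± 0.60 (edgeR adjusted p = 0.0447 for each). For Hill_BB_C309, C. tropicalis 1 was at 27.0 CPM, below all B. bassiana libraries (37.0 to 97.7), and C. tropicalis 2 at 435 CPM, without which the log2 fold was -0.99. Next were Hill_BB_C1826 at -2.98 ± 1.14 (0.0686 over the list alone, log2 fold -3.68 without B. bassiana 2) and Hill_BB_C15867 at -1.90 ± 0.89, which turned to 0.064 without C. tropicalis 3. As a list the defensins were lower by limma's camera (adjusted p = 0.00502), not with an estimated correlation (adjusted p = 0.0611), and lower by fry (adjusted p = 0.0158); the camera p exceeded 0.05 without B. bassiana 3 (0.0685) or C. tropicalis 2 (0.102). The low COX1 and COX2 library belongs to C. tropicalis, and with it and control 2 left out edgeR called 0 genes, where the median absolute log2 fold of the same 48 genes was 1.74 (1.79 with all libraries).

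The count of 48 moved with the libraries and the tool: edgeR called 0 genes without B. bassiana 1, C. tropicalis 1, C. tropicalis 4 or S. cerevisiae 1, 1 without B. bassiana 3, 10 to 23 without control 2 or 3, S. cerevisiae 2, 3 or 4 or C. tropicalis 3, 91 to 109 without B. bassiana 2 or 4 or C. tropicalis 2, and 0 in a fit of these 2 groups only or with the replicate number as a block. The median absolute log2 fold of these 48 genes, which were selected for their folds, was 1.71 to 1.92 without single libraries. DESeq2 called 700 (405 higher, 295 lower) and limma voom 1245. The 2 defensins adjusted over the list alone stayed at 2 without B. bassiana 2 and became 3 without C. tropicalis 1 and in DESeq2, and the count was 0 or 1 without any other library.

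Between B. bassiana and S. cerevisiae no gene passed in edgeR, and the lowest adjusted p was 0.0550. Among the genes at that value were the 2 with the lowest p in each direction, with no overlap between groups. They were LOC119648756 (67.5 ± 61.6 against 0.836 ± 0.202 CPM), LOC119654501 (23.5 ± 32.3 against 0.310 ± 0.151 CPM, from 3.43 to 71.2 CPM with B. bassiana, and a log2 fold of 6.24, or 4.63 without B. bassiana 1), LOC119656500 (21.7 ± 13.5 against 382 ± 143 CPM, log2 fold -4.14 ± 0.68) and LOC119656504 (8.18 ± 4.36 against 106 ± 37.2 CPM, log2 fold -3.69 ± 0.61). Of the defensins, 6 of 10 had folds below 0, led by Hill_BB_C309 at -1.20 ± 0.59 (edgeR adjusted p = 0.728) and Hill_BB_C1826 at -2.21 ± 1.14 (-2.92 without B. bassiana 2), none past the edgeR threshold over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05). DESeq2 and limma voom called 0 over all genes, and over the list alone limma voom called Hill_BB_C309 (log2 fold -1.45, adjusted p = 0.0371). The list did not pass in limma's camera (adjusted p = 0.0934). The edgeR fit gave 0 calls with 695 genes at an unadjusted p under 0.05, against 144 in DESeq2 and 199 in limma voom. Leaving out B. bassiana 1, 2 or 4 or control 1 gave 1, 9, 4 and 3 genes, and the camera p fell under 0.05 without B. bassiana 1 (adjusted p = 0.0256) or S. cerevisiae 1, and with the term for replicates 1 and 2 against 3 and 4 (adjusted p = 0.04996).

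The yeasts C. tropicalis and S. cerevisiae were compared last. No gene passed in edgeR, where the lowest adjusted p was 0.790. Hill_BB_C1619 was higher in all 4 C. tropicalis libraries than in any S. cerevisiae library (584 ± 163 against 327 ± 18.3 CPM, log2 fold 0.84 ± 0.31, edgeR adjusted p = 0.866 over all genes and 0.167 over the list alone). No defensin passed over all genes or adjusted over the list alone in edgeR (1 at an unadjusted p under 0.05, and 0 called over all genes in DESeq2 and limma voom). Folds of 9 of the 10 were above 0, with a median of 0.70, and limma's camera put the list higher (adjusted p = 0.0302), but not with an estimated correlation (adjusted p = 0.149). Of all genes, LOC119659430 (27.4 ± 8.50 against 9.18 ± 1.56 CPM, log2 fold 1.58 ± 0.30) and LOC119651827 (24.8 ± 3.05 against 14.3 ± 0.906 CPM) had the lowest p values on the higher side, and LOC119649290 (1.01 ± 0.770 against 43.6 ± 30.0 CPM) was among those on the lower, all at an adjusted p of 0.790. The edgeR fit gave 0 calls with 567 genes at an unadjusted p under 0.05, against 26 in DESeq2 and 4 in limma voom. The camera p exceeded 0.05 without S. cerevisiae 1, 2 or 3 or C. tropicalis 2, 3 or 4, reaching 0.565 without S. cerevisiae 1, and the list-alone count was 1 without B. bassiana 1.

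**Figure D4:**
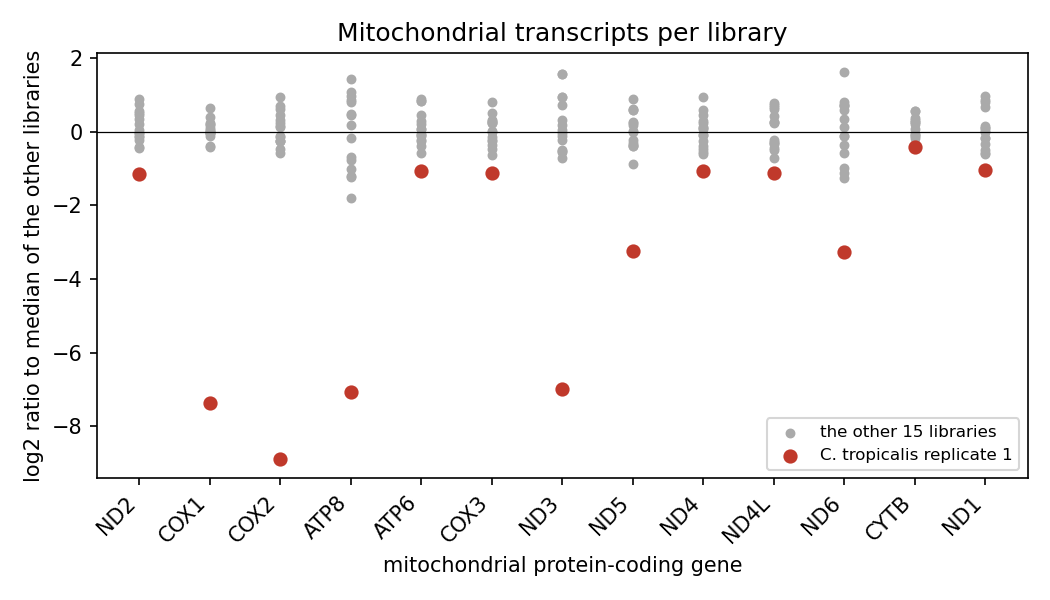
Log2 ratio of each of the 13 mitochondrial protein genes to its median in the other libraries, for each library; C. tropicalis replicate 1 is in red and the other 15 libraries in grey. In that library COX2 lies at -8.88 and CYTB at -0.41.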

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

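The tests of even mitochondrial loss, of mitochondrial content, of sequence difference, of random replicate pairings, of replicates 1 and 2 against 3 and 4 and of the 18 splits that balance them were chosen only after the result was seen. For each count of genes, the 8 libraries of a comparison were also divided in all 35 possible ways.

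Between B. bassiana and C. tropicalis 48 genes passed the threshold in a direct test of the difference between 2 treatments. Of the 35 splits, 1 (the real one) gave as many genes and the highest other count was 0, but replicates 1 and 2 differ from 3 and 4, and only 18 splits keep 2 of each on both sides, of which 1 gave as many (smallest possible share 0.0556), so chance cannot be excluded. Thinning keeps the expected ratios between libraries, so the folds could hardly fall and unequal depth stays open. The median absolute log2 fold of the 48 genes was 1.79, and 1.65 with all libraries thinned to one depth. At that depth 15 genes were called, 14 of them among the 48. Among the 48, 1 gene belongs to the 10 most abundant. Without it the median was 1.66, and 1.67 after those 10 genes were left out of the library sizes and the normalization. That refit called 63 genes. The folds of the other called genes therefore did not rest on these 10 abundant genes in the normalization. Called genes lay beside each other in one direction more often than by chance, in 2 adjacent pairs against a mean of 0.116 in 10000 random placings (permutation p = 0.0064), which may reflect shared local regulation or reads shared between neighbouring copies for those pairs, not for the other genes. A response to the fungus itself and the influence of single libraries stay open: without B. bassiana 1, C. tropicalis 1, C. tropicalis 4 or S. cerevisiae 1 and with the replicate block the count was 0 (median absolute log2 folds of the same 48 genes 1.71, 1.77, 1.72, 1.79 and 1.79), and why the calls ended was not tested, while the count was 52 with a block of replicates 1 and 2 against 3 and 4.

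Some mitochondrial transcripts were nearly missing from C. tropicalis replicate 1: COX1 at 53.8 CPM against 6686 to 10540 in the other 3 libraries of its group, and COX2 at 8.67 against 2896 to 6518. An even loss cannot be the whole cause, since COX1, COX2, ATP8 and ND3 kept under 1% of the median of the other libraries, ND5 and ND6 about 10%, ND2, ATP6, COX3, ND4, ND4L and ND1 44.8% to 48.8% and CYTB 75.1% (SD over genes of the log2 ratio 3.07, at most 0.699 in any other library). A lower mitochondrial content beside the near-total losses stays open. The library had the lowest share of mitochondrial mRNA (1.05%), but that share includes the genes nearly lost and cannot decide it. Of the 9 other protein genes 8 were below every other library. Its share of mitochondrial rRNA was also the lowest (2.72%, next lowest 4.11%), but 1 library of 16 is too few to tell. Reads moved to an annotated copy with few counts in the other libraries are argued against too, since genes over 4-fold above every other library gained 0.000636 of the CPM lost. A move to genes already abundant stays open, since they could take up such reads without rising 4-fold. Mitochondrial sequence that differs from the reference may account for the 4 genes under 0.1 of that median, but it cannot be told apart from a loss of these transcripts in the larvae without the reads, and no biological explanation was tested.

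B. bassiana and control libraries with the same replicate number deviated together, at a mean correlation over genes of 0.482. Depth stays open: the mean was 0.484 at one common depth, but thinning keeps the expected ratios between libraries, so the mean could hardly fall. A random pairing stays open too, since this pair of groups has the highest of the 6 means (permutation p of the highest = 0.0419, but 0.0543 for the mean over all 6). Replicates 1 and 2 stood apart from 3 and 4 in all 4 groups: in each group both had lower total counts and fewer genes detected at a common depth (exact permutation p = 0.00154 for each), ND4L was at 44.1 to 82.8 CPM against 97.5 to 143 over all groups, and an edgeR term for this split called 1350 genes, against at most 1 in 99 other placings of 2 libraries per group, so a batch shared by all 4 groups, of rearing, dissection or sequencing, may account for these values. Whether it reached the same genes everywhere stays open. The gene differences of B. bassiana and control correlated with those of S. cerevisiae and C. tropicalis at 0.574, which 2 of 36 placings reached (exact permutation p = 0.0556). The second of these 2 had the same 0.574 and no placing was higher, so this test could give no lower p and cannot decide it. A batch of each single number stays open too, at a mean over the 6 pairs of groups of 0.122. Dividing B. bassiana and control by these numbers gave 1650 genes, where the real split gave 0; of the 8 splits that part all 4 pairs the highest other count was 1, and blocking on the number left 0.

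For the other counts of genes over all those tested, 35 of 35 splits gave as many as the real 0, which chance can always reach. The highest count of another split was 0 for S. cerevisiae against control, 2 for C. tropicalis against control, 0 for B. bassiana against S. cerevisiae and 0 for C. tropicalis against S. cerevisiae. For genes changed alike by all 3 fungi, 100 of 100 regroupings reached the real 0 and the highest other was 0. Counts of antimicrobial genes over all genes were 0 in every split of all 6 comparisons. Adjusted over the list alone, the 2 defensins between B. bassiana and C. tropicalis were reached by 3 of 35 splits (highest other 2), so chance cannot be excluded. In the other 5 comparisons the real 0 was reached by 35 splits, with a highest other count of 1, or 0 for B. bassiana against S. cerevisiae. A camera p as small as the real one came from 8 of 35 splits for B. bassiana against control (real 0.0495, smallest other 0.000150), 30 for S. cerevisiae against control (0.862, 0.000205), 7 for C. tropicalis against control (0.0250, 0.000655), 11 for B. bassiana against S. cerevisiae (0.0934, 0.000105), 6 for B. bassiana against C. tropicalis (0.00502, 1.17e-08) and 11 for C. tropicalis against S. cerevisiae (0.0302, 5.12e-07), so chance is not excluded for any of these permutation counts.

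A direct test put Hill_BB_C309 at a log2 fold of -1.82 and Hill_BB_C6571 at -2.41 between B. bassiana and C. tropicalis, adjusted over the list alone. Single libraries far from the other 3 of their group were found for 15 of 120 groups of values, where chance gives about 6. The pseudogene share was 5.95% in control 2 against 0.530% to 1.11% in the other control libraries, and the long non-coding RNA share 1.34% in control 4 against 0.906% to 0.974%. B. bassiana replicate 1 had 19.4 CPM of Hill_BB_C13792 against 5.30 to 5.73, and 786 CPM of Hill_BB_C1619 against 283 to 326. B. bassiana replicate 2 had 97.7 CPM of Hill_BB_C309 against 37.0 to 40.4, and replicate 4 had 9.94 CPM of Hill_BB_C7985 against 0.989 to 1.35. S. cerevisiae replicate 1 was low in Hill_BB_C13792 (5.20 CPM against 7.76 to 8.13), Hill_BB_C1826 (0.321 against 0.887 to 1.06) and Hill_BB_C1827 (0.707 against 2.13 to 2.57). C. tropicalis replicate 1 had 1.08 CPM of Hill_BB_C7985 against 3.40 to 3.78. Hill_BB_C308 was counted in a lone library of each fungus group, at 6.004 CPM in B. bassiana 3, 3.50 CPM in S. cerevisiae 4 and 40.5 CPM in C. tropicalis 2, with 0 in the other 3.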

How the results depend on the processing

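The alternatives with surrogate variables, thinning, the block within 2 groups, the block of replicates 1 and 2 against 3 and 4, the 2 doubted libraries (C. tropicalis 1 and control 2), libraries of other groups left out, the list test between fungi and those of the list-alone count were chosen only after the result was seen. Beside the 48 genes between B. bassiana and C. tropicalis, edgeR called 60 with median-of-ratios factors, 50 with the stricter filter, 25 with no filter, 15 at one depth and 1045 with surrogate variables, and 0 with the 2 groups alone, with the replicate block (in all groups or within the 2 groups), or without the doubted libraries. With the block of replicates 1 and 2 against 3 and 4 it called 52, 45 of them among the 48. For B. bassiana against control, S. cerevisiae against control, C. tropicalis against control, B. bassiana against S. cerevisiae, B. bassiana against C. tropicalis and C. tropicalis against S. cerevisiae, DESeq2 called 150, 3, 13, 144, 700 and 26 genes and limma voom 1, 0, 0, 199, 1245 and 4. Surrogate variables gave 408, 0, 0, 391, 1045 and 19, and thinning gave 6 for B. bassiana against S. cerevisiae. Leaving out single libraries gave 0 to 11, 0 to 0, 0 to 0, 0 to 9, 0 to 109 and 0 to 0 genes. Genes alike under all 3 fungi were 1 in DESeq2 and 0 otherwise. The antimicrobial count over all genes for B. bassiana against C. tropicalis was 2 in DESeq2 and 1 in limma voom, and 0 without any single library.

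Over the list alone that comparison had 0 with no filter, with 2 groups alone, with the block within them and with surrogate variables, 3 in DESeq2 and without the doubted libraries, and 0 to 3 without single libraries. The list-alone count became 1 for S. cerevisiae against control in 2 groups alone, for C. tropicalis against control in DESeq2, and for B. bassiana against S. cerevisiae in limma voom and with the block within 2 groups; single libraries gave 0 to 1 for B. bassiana against control, S. cerevisiae against control and C. tropicalis against S. cerevisiae. The camera call of the antimicrobial list (1 list) went to 0 with an estimated correlation in each of the 4 comparisons that had it. For B. bassiana against control it also went to 0 with the stricter filter and without the doubted libraries. For B. bassiana against S. cerevisiae it became 1 with the replicate block, the block of replicates 1 and 2 against 3 and 4, and without the doubted libraries. Fry, which asks a different question, did not pass in 3 of the 4 comparisons with a camera call. It passed for B. bassiana against C. tropicalis. Single libraries left out gave 0 to 1 lists in all but S. cerevisiae against control (0). The replicate blocks changed no other call; of the pairs of groups, only B. bassiana and control met the mark for paired numbers, and 3 of their 4 libraries correlated best with their own number. Of 926 refitted log2 folds of named genes 841 kept their side of the threshold and sign, 44 passed it newly, 35 no longer did and 6 reversed: Hill_BB_C1619 (B. bassiana against S. cerevisiae) at -0.075 without B. bassiana 1 (up to 0.54 without single libraries); Hill_BB_C15867 without C. tropicalis 3, at 0.064 (B. bassiana against C. tropicalis, down to -2.25 without single libraries and -2.89 with surrogate variables) and -0.47 (C. tropicalis against S. cerevisiae, up to 1.87); Hill_BB_C308 (C. tropicalis against S. cerevisiae) at -2.81 in limma voom, -2.52 with surrogate variables and from -6.89 without C. tropicalis 2 to 10.24 without S. cerevisiae 4. Apart from fewer libraries or genes in a fit, the cause was not tested. Depth limits mainly rare defensins such as Hill_BB_C1826, at 0.161 to 1.38 CPM in the group means, where 3 counts stand for 0.106 to 0.449 CPM per library.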

Other observations

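LOC119647826, singled out after its values were seen, was among the 10 most abundant transcripts of the fat body, with 4 control libraries between 3840 and 74490 CPM, and B. bassiana libraries between 37.8 and 1809 CPM. Its log2 fold against control was -5.50 ± 1.12 (edgeR adjusted p = 0.151), and -5.76 against C. tropicalis, where it passed the threshold. Over the 10 most abundant genes, which include ribosomal RNA genes and a pseudogene, the median log2 fold of B. bassiana was -0.95 against control, -0.97 against S. cerevisiae and -0.65 against C. tropicalis. The 10 most abundant genes of each library, chosen library by library, took 23.0 ± 3.50% of counts with B. bassiana and 30.8 ± 7.30% in the control (SD, n = 4 each).

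Genes with a value more than 8-fold from the nearest other library gathered in a few libraries. Control 2 had 24 such genes on the low side, C. tropicalis 1 had 18 and B. bassiana 1 had 17, and C. tropicalis 2 had 23 on the high side. Control 1 had 11 high and 13 low.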
